A study of Euplotes vannus with 9 samples.

How the data were processed

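The 9 samples were total RNA of Euplotes vannus collected at 0, 1 and 12 h of exposure to 15 mg/L silver nanoparticles, 3 libraries per time, extracted with TRIzol and made into paired-end libraries with a NEBNext Ultra RNA kit, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether replicates of a time came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

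The authors deposited a table of FPKM values with a column per library, rounded to hundredths. Per the submitters' processing notes edgeR 3.6 was used, with no role given. The assembler, the aligner, the counting tool, any filter and how strand was handled are not given in the sources used here. The identifiers have the form of de novo assembly components, and nothing used here pairs them with gene names. The 16 functional gene lists fixed before the data were examined could therefore not be matched, and their tests were not run. Components that share sequence (paralogs, or fragments of the same gene) can share reads, so values of single components are uncertain to that extent. A component may also come from another organism in the culture, which was not tested.

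FPKM values are not counts, so no count model was used. Values were transformed to log2(FPKM + 1), with a pseudocount of 1, which understates the change of low components. Components at 1 FPKM or more in at least 3 of the 9 libraries were kept. A linear model with a mean per time was fitted to all 9 libraries in limma 3.58.1 (R 4.3.3) with a trended, robust variance prior, and 1 h against 0 h, 12 h against 0 h and 12 h against 1 h were tested, with an F test over the 3 times. P-values were adjusted by the Benjamini-Hochberg method over the 24883 components in each comparison, and components with an adjusted p under 0.05 were called changed. Values per library, such as a share of the total, were compared by exact two-sided permutation tests, which cannot go below 0.1 with 3 libraries against 3.

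Named components were chosen by a rule fixed before the data were examined, as were the tests, the time patterns and the alternatives except those said to be added. For a table without gene names it took 1 component that rose most and 1 that fell most at 1 h and likewise at 12 h against 0 h, among those called, with a mean of at least 5 FPKM in the higher group and no overlap between the groups' libraries, skipping a component already named. The dominant component was named outside this rule.

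Simulated libraries with the real means and the model's moderated spreads, drawn independently for each component, were used to test the model. In them 200 components with a mean above 5 FPKM on the log2(FPKM + 1) scale were changed at 12 h, far fewer than were called in the data. In the comparison of 12 h with 0 h over 24883 components, 71% of the 100 components changed 2-fold and 99% of the 100 changed 4-fold were recovered, with 14 wrong calls. Recovery of lower components, which were most of those tested, was not measured. Relative depth was estimated from components with low values in few libraries (at least 0.3 FPKM in both libraries of a pair, detected in at most 4 libraries), in which the ratio of values that occurs most often is the inverse ratio of depths. Of the 36 pairs of libraries, 34 gave ratios within 0.05 (log2) of the fitted depths, and on simulated data of 40000 components the largest error was 0.11%. Relative to the shallowest library, depths were 1.12, 1.37 and 1.23 for 0 h replicates 1 to 3, 1.27, 1.00 and 1.51 for 1 h replicates 1 to 3, and 1.39, 1.34 and 1.46 for 12 h replicates 1 to 3. The totals of the deposited FPKM ranged from 1211023 to 1393156 per library. No interval or detection limit that needs counts is given, since the absolute depth is unknown.

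Alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, rescaling to equal totals, median-of-ratios size factors, quantile normalization, only the 6 libraries compared, the replicate number as a block, limma without trend or robust prior, stricter thresholds, and leaving out each library. Leaving out the dominant component before rescaling, and leaving out 1 h replicate 3 and 12 h replicate 2 together, were added after seeing the data. Replicate numbers paired the libraries only in part. The correlation of same-numbered libraries' deviations from their time means ranged from -0.18 to 0.53, with the replicate 1 libraries at 0.45 to 0.53. The main model left the replicate number out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.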

Results

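Transcript abundance was profiled in Euplotes vannus, a single-celled marine ciliate that lives on the sea bed and is grown as clonal cultures in artificial seawater. The cultures were exposed to silver nanoparticles (AgNPs), metallic silver particles that release silver ions, at 15 mg/L, and whole cells were sampled at 0, 1 and 12 h of exposure. Each time was represented by 3 paired-end RNA-seq libraries, 9 in all. Abundance was given as FPKM, a fragment count divided by gene length and by the number of mapped fragments, for 91343 assembled transcript components, which stand for genes here. The components carry assembly identifiers without gene names, so they are described by level and by time course, and no chromosome position or annotation is given. Of these, 4866 were at 0 in every library, and 24883 reached 1 FPKM in at least 3 libraries and were tested. No unexposed library at 1 h or 12 h was among the 9, so a difference between times covers both the exposure and the elapsed time in culture.

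The libraries grouped by exposure time. The correlation of log2(FPKM + 1) across components ranged from 0.931 to 0.979 between libraries of the same time and from 0.857 to 0.943 between libraries of different times. The first principal component held 47.2% of the variance and placed the 12 h libraries apart from the others, and the second held 20.8% and placed the 1 h libraries apart. The number of components at 1 FPKM or more per library was 23107 ± 339 at 0 h, 24979 ± 1738 at 1 h and 24504 ± 1152 at 12 h (SD, n = 3). The exact two-sided permutation p was 0.1 for 1 h against 0 h, the smallest that 3 libraries against 3 allow, and 0.2 for 12 h against 0 h. The absolute depth is unknown, because FPKM values carry no read counts. The relative depth, estimated from the steps between low FPKM values, differed by at most 1.51-fold among the libraries, from 1 h replicate 2, the shallowest, to 1 h replicate 3, the deepest.

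**Figure D1:**
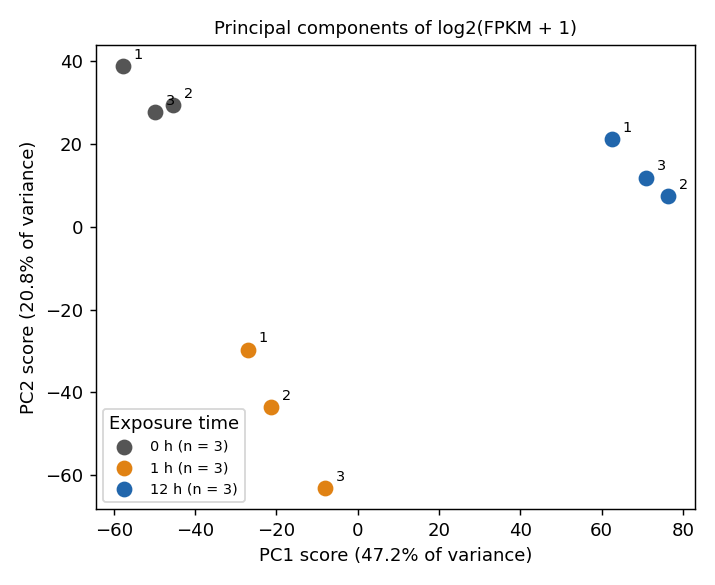
Scores of the 9 libraries on the first principal components of log2(FPKM + 1) over 24883 components, without units. Each point is a library with its replicate number and colours mark the exposure time (n = 3 each). The 12 h libraries lie apart on PC1 (47.2% of the variance) and the 1 h libraries on PC2 (20.8%).

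A single component, c41880.graph_c0, chosen for mention after its values were seen, dominated the FPKM totals. It stood at 349767 ± 31163 FPKM at 0 h, 338182 ± 58040 at 1 h and 514267 ± 76408 at 12 h (SD, n = 3), which was 27.5% ± 2.7, 26.1% ± 6.0 and 39.8% ± 5.4 of the library total. Its share at 12 h exceeded its share at 0 h in every library (exact two-sided permutation p = 0.1, the smallest possible). FPKM is divided by length, so this is a share of FPKM and not of reads. On the log2 scale the difference at 12 h against 0 h was 0.55 ± 0.19 (SE; limma adjusted p = 0.042). This call was not stable, since 12 of 20 alternatives lost it, among them median-of-ratios scaling (0.60 ± 0.25, limma adjusted p = 0.077) and leaving out any of the 0 h libraries, 1 h replicate 2, or 12 h replicate 1 or 2. Whether this component is a messenger or a structural RNA is not given in the sources used here. The balance of rises and falls among the other components depended on whether it counted toward the library total, so both splits are given for each comparison.

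The comparison of 1 h with 0 h asked which transcripts differed first after exposure began. Of the 24883 components tested, 3399 (13.7%) changed at a limma adjusted p under 0.05, of which 1628 were higher and 1771 lower at 1 h. The changes were mostly moderate, with a median log2 fold change of 0.90 among the components that rose and -0.90 among those that fell. At least 2-fold changes numbered 615 rises and 720 falls. At least 8-fold changes were few, with 18 rises and 15 falls. The largest rise was in c30192.graph_c0, from 28.7 ± 5.9 FPKM at 0 h to 3835 ± 158 at 1 h (SD, n = 3), a log2 fold change of 7.03 ± 0.28 (SE; limma adjusted p = 2.1e-07), or 131-fold on the FPKM + 1 scale. The largest fall was in c47155.graph_c0, from 120.1 ± 17.6 FPKM to 7.78 ± 3.04, a log2 fold change of -3.83 ± 0.24 (limma adjusted p = 1.6e-06), or 14.2-fold. Among the 100 most abundant components, 2 were higher, 6 lower and 92 not called with the authors' scaling. With c41880.graph_c0 left out and the libraries rescaled, 5 were higher and 11 lower.

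Under all 5 scalings tried, 2341 components were called in the same direction at 1 h, 911 higher and 1430 lower. These numbers are capped by the scaling with the fewest calls, 1065 rises and 1531 falls with c41880.graph_c0 left out. No component was called in opposite directions by different scalings. That says little, because all but quantile normalization only multiply each library by a constant, which could hardly turn a call around. Falls made up 52.1% of the calls with the authors' scaling, 63.1% with median-of-ratios factors and 59.0% with c41880.graph_c0 left out. The count rested partly on 2 libraries: it was 1813 without 0 h replicate 3 and 1852 without 1 h replicate 2, with 833 and 787 rises. Without 0 h replicate 2 it was 2311, with 981 rises. With the replicate number as a block it was 5135, with 2667 rises, so that falls made up 48.1%; they also made up less than 50% without 0 h replicate 1 (48.6%) or 1 h replicate 1 (49.3%), so neither direction held a stable majority at 1 h.

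The comparison of 12 h with 0 h covered the state after prolonged exposure. More components differed than at 1 h: 8798 (35.4%) were called, 3628 higher and 5170 lower at 12 h (limma adjusted p under 0.05). Rises had a median log2 fold change of 0.98 and falls one of -0.93. At least 2-fold changes numbered 1749 rises and 2184 falls, and at least 8-fold changes 59 rises and 55 falls. With c41880.graph_c0 left out and the libraries rescaled, at least 2-fold changes numbered 2959 rises and 1473 falls. The largest rise not already named was in c47496.graph_c0, from 7.25 ± 0.82 FPKM at 0 h to 277 ± 55.2 at 12 h (SD, n = 3), a log2 fold change of 5.06 ± 0.20 (SE; limma adjusted p = 2.0e-08), or 33.3-fold. The largest fall was in c44449.graph_c0, from 611 ± 163 FPKM to 10.0 ± 0.9, a log2 fold change of -5.76 ± 0.23 (limma adjusted p = 2.3e-08), or 54.2-fold. Neither of these was called at 1 h: c47496.graph_c0 had a log2 fold change of 0.48 ± 0.20 (limma adjusted p = 0.13) and c44449.graph_c0 one of -0.54 ± 0.23 (limma adjusted p = 0.14). By contrast, c47155.graph_c0 was still low at 12 h, at 4.43 ± 0.99 FPKM.

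The calls at 12 h were spread over all levels of abundance. In the lowest of 5 equal level classes of the tested components, with a median of 1.21 FPKM, 669 were higher and 514 lower, so 23.8% were called. In the highest class, with a median of 34.0 FPKM, 836 were higher and 1538 lower, so 47.7% were called. The classes were counted with the authors' scaling only, so their balance of rises and falls holds for that scaling. Among the 100 most abundant components, 8 were higher and 27 lower with the authors' scaling, while with the dominant component left out and the libraries rescaled 21 were higher and 22 lower.

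The balance of rises and falls at 12 h depended on the scaling. Falls made up 58.8% of the calls with the authors' scaling, 55.5% with median-of-ratios factors and 37.1% with c41880.graph_c0 left out and the libraries rescaled. Without 12 h replicate 3, the rises numbered 2267 and falls made up 67.0% of the calls. Over all tested components the median log2 change moved from -0.08 to 0.12 between the first and the last of these. In the same direction under all 5 scalings were 6152 components, 3154 higher and 2998 lower. Of these, 1459 were at least 2-fold higher and 1424 at least 2-fold lower in every scaling. The totals are capped by the scalings with the fewest calls, 3296 rises with equal totals and 3075 falls with c41880.graph_c0 left out. Their near balance is therefore not a split free of scaling. No component was called in opposite directions, but multiplying libraries by constants could hardly turn a call around.

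**Figure D2:**
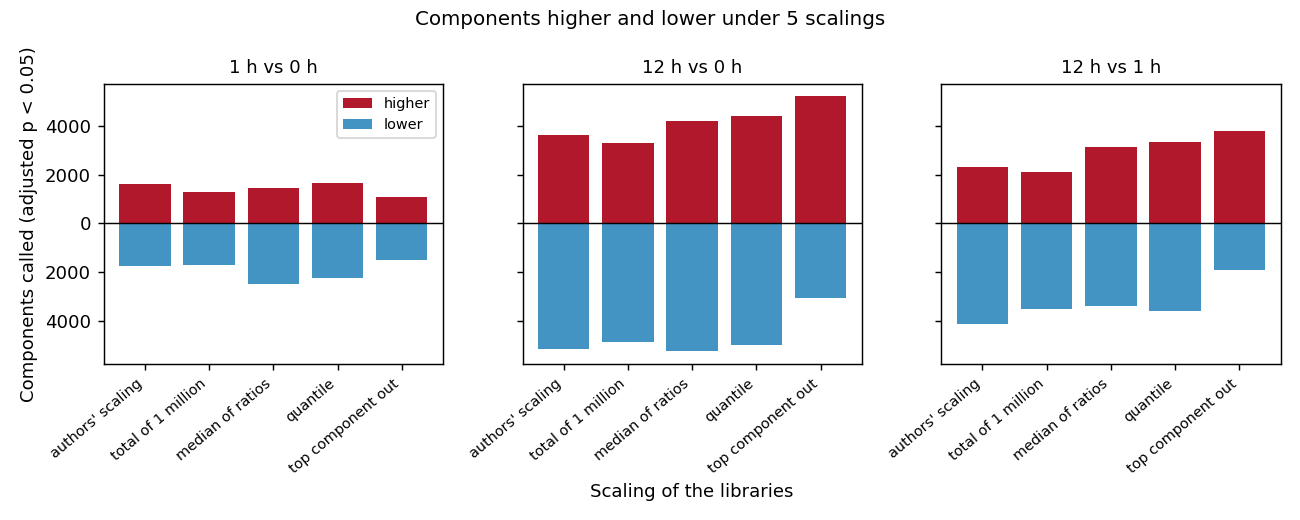
Numbers of components called higher (bars above 0) and lower (bars below 0) at a limma adjusted p under 0.05 in each comparison, for 5 scalings of the libraries. At 12 h against 0 h, 3628 were higher and 5170 lower with the authors' scaling, against 5222 higher and 3075 lower with the dominant component left out.

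The comparison of 12 h with 1 h tested directly whether levels differed between the later and the earlier time. It called 6440 components (25.9%), 2296 higher and 4144 lower at 12 h than at 1 h (limma adjusted p under 0.05), and 190 of them rose and 114 fell at least 4-fold. Both components named for 12 h differed between the exposure times: c47496.graph_c0 was higher at 12 h by 4.58 ± 0.20 on the log2 scale (limma adjusted p = 8.5e-08) and c44449.graph_c0 fell by 5.22 ± 0.23 (limma adjusted p = 8.5e-08). The component that rose most at 1 h, c30192.graph_c0, had come down to 1610 ± 827 FPKM at 12 h, a log2 change of -1.36 ± 0.28 from 1 h (limma adjusted p = 0.0041), and was still 50.7-fold above 0 h. For c47155.graph_c0 the change from 1 h was -0.65 ± 0.24 (limma adjusted p = 0.059). Falls made up 64.3% of the calls with the authors' scaling, 51.9% with median-of-ratios factors and 33.7% with c41880.graph_c0 left out. Without 12 h replicate 3, the rises numbered 1461 and falls made up 71.4% of the calls. In the same direction under all 5 scalings were 3925 components, 2059 higher and 1866 lower. These are likewise capped by the smallest counts, 2126 rises with equal totals and 1920 falls with c41880.graph_c0 left out.

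**Figure D3:**
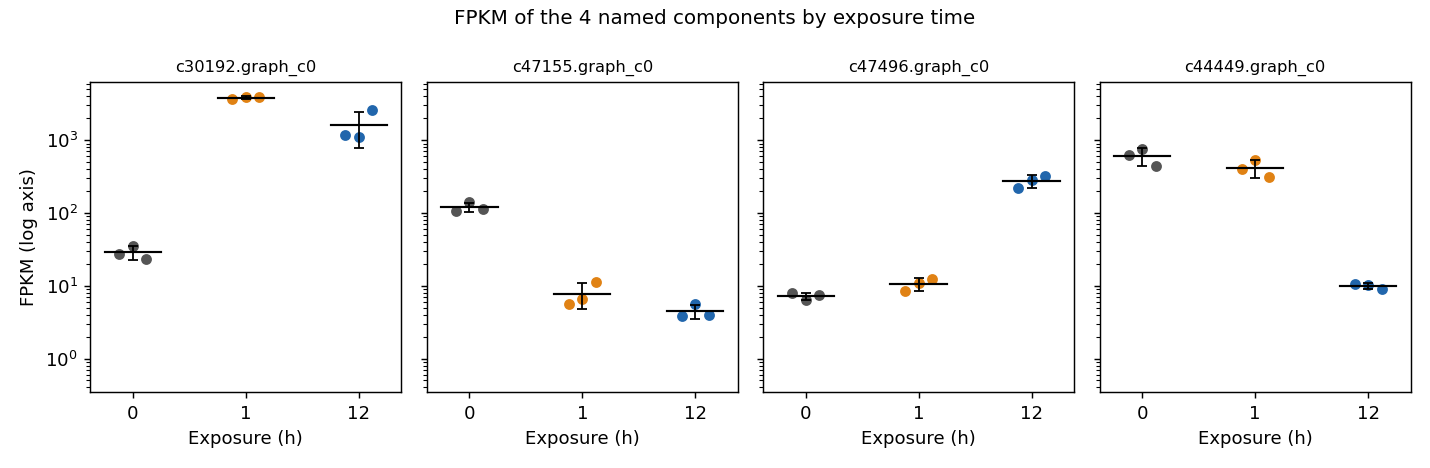
FPKM on a log axis of the 4 named components at 0, 1 and 12 h of exposure. Points are libraries (n = 3 per time), horizontal lines are means and error bars are SD. c30192.graph_c0 rose from 28.7 to 3835 FPKM at 1 h, while c47496.graph_c0 and c44449.graph_c0 moved mainly between 1 h and 12 h.

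Across the 3 times together, 9908 components (39.8%) changed by limma's F test at an adjusted p under 0.05. Separately from this test, the tested components were sorted by their calls in the 3 comparisons into groups fixed beforehand. The sustained group, called in the same direction at 1 h and 12 h, held 2006 components, or 59.0% of those called at 1 h, with 701 higher and 1305 lower. With c41880.graph_c0 left out and the libraries rescaled it held 616 higher and 923 lower, and with median-of-ratios factors 733 and 1710. With the authors' scaling, its higher members had median log2 fold changes of 0.97 at 1 h and 1.05 at 12 h, and its lower members -0.95 and -1.15. For 135 of the higher and 270 of the lower members the change was further extended at 12 h against 1 h, and for 59 and 64 it was partly reversed. The transient group, called at 1 h, called in the reverse direction between 1 h and 12 h and not called at 12 h against 0 h, held 762 components (22.4% of those called at 1 h). Of these, 538 were higher at 1 h, with a median log2 fold change of 0.90 at 1 h and -0.01 at 12 h, and 224 were lower, with -0.93 and -0.05. With c41880.graph_c0 left out and the libraries rescaled, the transient group held 254 higher and 324 lower components, so its direction depended on the scaling.

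The late group, not called at 1 h but called at 12 h against both 0 h and 1 h, was larger, with 3714 components. In all, 6657 components were called at 12 h and not at 1 h. Those outside the late group, 1368 higher and 1575 lower, were not called between 12 h and 1 h. The same held for 496 of the 1258 called at 1 h and not at 12 h, so the groups leave these unresolved. The late group held 1511 higher and 2203 lower components with the authors' scaling, and 2568 higher and 999 lower with c41880.graph_c0 left out. Late risers had median log2 fold changes of 0.06 at 1 h and 1.11 at 12 h, and late fallers -0.03 and -0.99. As a share of the FPKM total without c41880.graph_c0, the late risers made up 2.55% ± 0.22 at 0 h, 2.63% ± 0.25 at 1 h and 7.77% ± 0.14 at 12 h (SD, n = 3). The late fallers made up 17.7% ± 1.7, 17.4% ± 0.8 and 9.11% ± 0.39, and the sustained fallers 9.66% ± 0.46, 4.61% ± 0.58 and 4.83% ± 0.30. The groups were chosen on these same libraries, so the shares describe them and are not independent evidence of their direction. The sustained group held 1069 components without 0 h replicate 3 and 1206 without 1 h replicate 2, and the transient group 473 and 350.

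**Figure D4:**
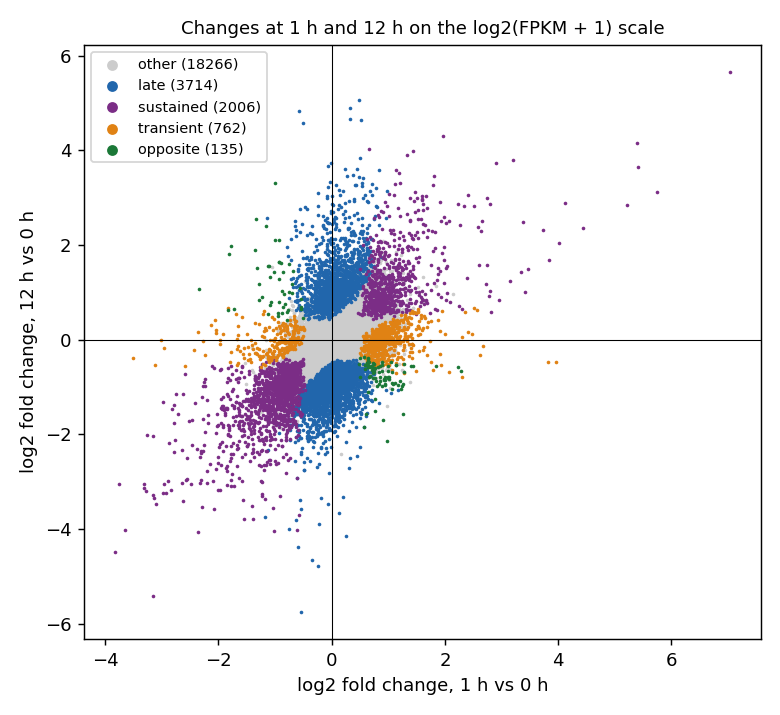
Log2 fold change at 12 h against 0 h (vertical axis) plotted against that at 1 h against 0 h (horizontal axis) for the 24883 tested components, on the log2(FPKM + 1) scale with the authors' scaling. Each point is a component and colours mark the time patterns, with 3714 late, 2006 sustained, 762 transient and 135 components called in opposite directions at the different times.

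The changes at 1 h and at 12 h were measured against the same 0 h libraries, which by itself makes them correlate. Across components, which are not independent replicates, Pearson's r of the fold changes was 0.54, against a mean of 0.50 and a highest value of 0.52 in 100 simulated sets of unchanged groups that shared their controls. The simulation drew components independently, while 49.2% of the variance between libraries of the same time lay along a single axis. The simulated range of r can therefore be too narrow, and no conclusion is drawn from it. Whether r exceeded its simulated values also depended on the settings. It was above the highest of them in 12 of the 18 alternatives that move r, between the mean and the highest in 2 (a pseudocount of 5 and a filter at 5 FPKM), and below the mean in 4: no filter (0.487 against 0.4996) and 0 h replicates 1, 2 and 3 left out in turn (0.535, 0.558 and 0.549 against 0.599, 0.601 and 0.599). Leaving out libraries moves the simulated mean by itself, because it changes the group sizes. That mean was 0.599 to 0.601 without a 0 h library and 0.443 to 0.453 without an exposed one. It was 0.396 without 1 h replicate 3 and 12 h replicate 2. The observed r stayed at 0.490 to 0.558 with a library left out. Where r fell above or below in these cases therefore reflects mainly the group sizes. The covariance was 0.227 against 0.037 in the simulation, a difference of 0.190. The size of this difference depended on the settings: simulated anew at each, it was 0.318 and 0.088 with pseudocounts of 0.1 and 5 and 0.049 with no filter. Calls shared by both times numbered 701 rises and 1305 falls, against 0 in 20 simulated sets of unchanged groups, which hold no effects and so almost no calls, and 237 and 368 for independent lists of the same lengths, which leave out the shared controls. The excess over either is therefore no measure of a shared effect. The 3 control libraries could not be split into sets of at least 2, so part of the excess may come from them.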

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

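The tests of sequencing depth and exposure time for components seen in a single library, and those of the replicate number and of response progress below, were chosen after the result was seen. Leaving out the most abundant component was also added after seeing the data, though its bound was written before its result. The tests of a scaling offset and of depth along the shared axis were set down before their results.

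The level at 12 h differed from that at 1 h, by the direct test between these times, in 3 of the 4 named components: c30192.graph_c0 by -1.36, c47496.graph_c0 by 4.58 and c44449.graph_c0 by -5.22 on the log2 scale. In 135 components the changes at 1 h and 12 h were called in opposite directions. Of these, 87 were higher at 1 h and lower at 12 h, with median log2 fold changes of 0.83 and -0.66, and 48 were lower and then higher, with -0.93 and 1.05. These counts hold for the authors' scaling and were not repeated with other scalings or with a library left out. The transient group turned from 538 higher and 224 lower to 254 and 324 with c41880.graph_c0 left out. The excess of rises at 1 h among the 135 may likewise depend on the scaling.

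Components left out of the tests showed a signal in exposed libraries above that in the 0 h libraries. The number at 1 FPKM or more in a single library was at most 942 in a 0 h library, but 3182 in 1 h replicate 3, 3242 in 12 h replicate 2, 1496 in 1 h replicate 2 and 1225 in 12 h replicate 3. Their levels were low, with medians of 1.30 FPKM in 1 h replicate 3 and 1.32 in 12 h replicate 2. Greater sequencing depth is argued against for 12 h replicate 2: 3 libraries of the same or greater relative depth had fewer than 0.5 times as many. For 1 h replicate 3, the deepest library, no other library was as deep. The 3 libraries within 10% of its depth were shallower and had fewer than 0.5 times as many, which leaves a part for depth open. The bound written for time of exposure was a library of that time below the highest 0 h library, which would count against it. That bound was met at both times, by 1 h replicate 1 with 886 and 12 h replicate 1 with 762. It rests on a single library per time, and 4 of the 6 exposed libraries lay above every 0 h library, so time of exposure is left open. RNA or DNA of other organisms in these cultures stays open, untested without sequences.

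Falls outnumbered rises at 12 h against 0 h with the authors' scaling, at 58.8% of the calls. With the most abundant component left out and the libraries rescaled, falls made up 37.1% of the calls, and 31.1% to 41.2% when a library was left out as well. This does not test whether the total taken up by that component is the cause, because rescaling moves all other components alike, by 0.25 on the log2 scale at 12 h against 0 h, more than the median change of -0.08 that it turns. A scaling offset between libraries was tested with median-of-ratios factors, which gave 55.5% falls, from 53.7% to 57.9% with a library left out. Falls above 50% had been set beforehand as evidence against an offset, but that bound was a poor one, because such factors centre the median change near 0 (-0.05) whatever the offset, so neither explanation can be told apart from a true excess of falls. A biological increase of the dominant transcript with exposure stays open, as does a difference in how RNA was selected for sequencing, and which split is meaningful depends on whether that component is a structural RNA, which was not known here.

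Differences between libraries of the same time fell largely along a single axis, which held 49.2% of the within-time variance. Its loadings were -0.35, -0.50 and -0.28 for replicate 1 at 0, 1 and 12 h, and 0.27 for 0 h replicate 2, 0.54 for 1 h replicate 3 and 0.39 for 12 h replicate 2. For a batch marked by the replicate number, the lowest correlation between same-numbered libraries was -0.18, which argues against a batch in every number. The replicate 1 libraries correlated at 0.45 to 0.53, so a batch shared by them stays open. Progress of the exposure response is argued against, because the axis shared at most 1.93% of its variance across components with the fold changes at 1 h or 12 h. For sequencing depth, r within times was 0.43 over 9 libraries (exact permutation p = 0.5). Spearman's rho was 0.35 (exact permutation p = 0.52), and r was 0.26 without the 2 libraries farthest in depth. These are too few libraries to decide. Beyond progress of the response, no biological explanation was tested.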

How the results depend on the processing

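The settings added after seeing the data were leaving out the dominant component, leaving out 1 h replicate 3 and 12 h replicate 2 together, and simulating shared controls at each setting. In the comparison that named it, each of the 4 named components kept its direction and call in all 21 alternatives, with largest limma adjusted p values of 8.5e-06 for c30192.graph_c0, 5.2e-05 for c47155.graph_c0, 2.2e-06 for c47496.graph_c0 and 2.9e-06 for c44449.graph_c0. Elsewhere they kept direction in all 21, but c44449.graph_c0 at 1 h was called with the replicate block and c47155.graph_c0 at 12 h against 1 h in 4 alternatives. c41880.graph_c0 was higher at 12 h in 19 of 20 alternatives and called in 8 against 0 h; quantile normalization fixes its change at 0. With no filter on low values, calls fell to 1062 at 1 h against 0 h, 4216 at 12 h against 0 h, 2686 at 12 h against 1 h and 4538 by the F test, and the sustained, transient and late groups to 650, 220 and 1589; the cause was not tested. At an adjusted p under 0.01 these numbers were 1526, 5128, 3490, 5782, 919, 316 and 2054, by construction. Requiring a 2-fold change left 1335, 3933 and 2683 calls in the comparisons and 707, 245 and 1495 components in the groups, and limma's treat test against a 1.5-fold minimum 432, 1977 and 1215 calls. With the replicate block, calls at 1 h rose to 5135 (2667 rises) and the transient group to 1192. The numbers paired the libraries only in part, and 5 of the 9 libraries correlated best with their own number. The block kept the calls of the other comparisons, the F test and the sustained and late groups within 1.5 times (10912 calls at 12 h against 0 h). When each library was left out in turn, calls at 1 h ranged from 1813 to 3586, the sustained group from 1069 to 2026 and the transient group from 350 to 766, and the total counts for the other comparisons, the F test and the late group stayed within 1.5 times, while the rises at 12 h fell to 2267 against 0 h and 1461 against 1 h without 12 h replicate 3. The correlation of the 1 h and 12 h fold changes ranged from 0.490 to 0.558 and their covariance from 0.210 to 0.247. The correlation was 0.487 with no filter and 0.517 without 1 h replicate 3 and 12 h replicate 2. The covariance was 0.403 and 0.102 with pseudocounts of 0.1 and 5, 0.0780 with no filter, 0.309 with a filter at 5 FPKM and 0.215 after rescaling to equal totals. Without 1 h replicate 3 and 12 h replicate 2, calls were 3413, 8477 and 5194 in the comparisons. Components at 0.1 FPKM or more numbered 39273, 44176 and 47031 per library on average at 0, 1 and 12 h, the same order of 0 h below both exposed times as at 1 FPKM. The planned tests of gene lists could not be run without gene names.

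Other splits of the libraries were counted for each comparison. For the F test, 100 of 280 splits into groups of 3 were used, the real one among them. It gave 9908 calls and the others at most 4366. This argues against chance in how libraries were grouped, not against differences between cultures or batches, since replicates may be technical. For single comparisons only 10 splits exist, too few for a share under 0.05: the real split gave 3399 calls at 1 h against 0 h, 8798 at 12 h against 0 h and 6440 at 12 h against 1 h, and the highest other split 1, 0 and 0, with 1 of the 10, the real one, as large in each.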

Other observations

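Components of the same assembly graph changed together. Among the tested components were 1075 pairs that share a graph number, which an assembler gives to connected sequences. The log2 fold changes of such pairs correlated with r = 0.54 at 12 h against 0 h, while 1000 sets of random pairs matched on mean level gave at most 0.13. At 1 h against 0 h, r was 0.54 against at most 0.12. Pairs are not independent replicates. Shared sequence or shared regulation within a graph is a candidate explanation, set down before the result was seen, and the data do not separate them: reads divided between similar components would give the same pattern.

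Few components switched between absence and presence. Between 0 h and either later time there were 8 cases of a component at 0 in every library of a time and at 1 FPKM or more in all 3 of the other. With under 0.1 FPKM in place of 0 there were 19 cases. A component that switched against 0 h at both later times counts once for each, so the components may be fewer.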
